A study of Mus musculus with 5 samples.

How the data were processed

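RNA labelled as from the visceral fat of male C57BL/6 mice was sequenced in 5 libraries. Per the labels, 1 library came from a control mouse on standard chow with vehicle, 2 from diabetic mice with vehicle and 2 from diabetic mice given curcumin. Diabetes was induced by streptozotocin, a toxin of insulin-producing cells, at 70 mg/kg and 2 days of age, followed by a diet with 60% of its energy from fat from 3 weeks of age for 8 weeks. Curcumin, a polyphenol of turmeric, was given by mouth at 50 mg/kg per day for 28 days from 11 weeks of age. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these libraries, which may in part be technical.

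The libraries were made with a strand-marking poly-A kit and read as paired ends, per the labels' protocols. The authors deposited whole-number counts per gene, not normalised, in a single table of 78334 Ensembl genes. The submitters' processing notes name FastQC, featureCounts and the mouse build GRCm39; the aligner, the annotation release and the strand setting of the counting are not given in the sources used here. Without the strand setting, reads of overlapping antisense genes cannot be assigned with certainty, and near-identical family members such as the defensins, Saa1 and Saa2, and immunoglobulin genes may share reads. Symbols were matched by gene ID for 51486 genes (65.7%), which held 95.3% to 98.5% of each library's counts. No coordinates were used, because the reference at hand was GRCm38; it served for GC content only.

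Total counts ran from 25378046 to 42422890 per library. A count of 0 allows up to 3 counts, or 0.118 CPM (counts scaled to the library total) in the shallower libraries and 0.0707 CPM in the deepest. Shares of counts carry 95% Wilson intervals. These limits and intervals cover counting error only, since the reads have no molecular identifiers. A count of 0 can leave room for more where few molecules were copied many times: of the genes with 15 to 40 counts (scaled to a total of 25000000) in curcumin-treated 2, 27.3% were at 0 in diabetes 1 and 8.32% to 21.3% in the other libraries.

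Genes were kept by edgeR's filterByExpr, which left 29855, and scaled by TMM. The 3 comparisons (curcumin-treated against untreated diabetes, diabetes against control, curcumin-treated against control) were fitted in a single model of all 5 libraries with edgeR 4.0.16's quasi-likelihood test in R 4.3.3 (robust, with the newer dispersion method), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model had 2 residual degrees of freedom, and the single control library was assumed to vary like the other groups. The biological coefficient of variation was 1.07. Standard errors are the fold change over the square root of the F statistic, and fitted fold changes use a prior count of 0.125. CPM values use the TMM factors, with the exceptions that follow. The CPM of Gpx5, Akr1b7, Crisp1, Lcn8, Spag11b and Prm2 and the limits for a count of 0 are scaled to the library total alone, as are shares of all counts. Levels on the log2 scale use a prior count of 2 unless stated otherwise.

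For gene groups, 40 lists of pathways, cell types and other tissues were fixed before the data were examined. Of their 700 genes, 699 were found, and 39 lists had at least 5 tested members. Each was tested with camera in limma 3.58.1 at a preset correlation of 0.01, which compares a list with the other genes, then with an estimated correlation, and with fry, which asks whether a list's genes move one way on balance. Named genes followed a rule also fixed before the data were examined, for the first 2 comparisons: genes past the threshold with libraries that do not overlap and, where none passed, the 5 with the smallest p per direction among named, non-overlapping genes with a mean log2 CPM of at least 1. Added to these were up to 4 members per list by smallest p, and 13 genes reported in each comparison. The third comparison names genes by the same rule, which was extended to it. Marker genes of the epididymis, sperm and smooth muscle, genes leading a library, and Klrb1c were named after their values were seen.

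The correlation of the diabetes difference with the curcumin difference was set beside 100 simulations in which the curcumin-treated and untreated diabetic libraries had equal means, since both differences share the diabetic libraries. Alternatives were other scalings, low-count filters, thresholds, DESeq2 1.42.0, limma-voom, the older quasi-likelihood method, a fit without robust moderation, removal of other-tissue, immunoglobulin and mitochondrial genes, a replicate block, a fit of 4 libraries, and leaving out each replicated library. A crossed pairing, an adipocyte covariate and a GC correction were chosen after seeing the data. GC content came from the longest GENCODE transcript per gene, known for 82.7% of the tested genes.

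The test was run on simulated counts with 200 changed genes in the curcumin comparison. At a dispersion of 0.04 it recovered 100% of the genes changed 4-fold, 16-fold or 64-fold, with 13 false calls among 25201 genes. At the dispersion of these libraries it recovered 0% at each of these sizes among 26540 genes. In the list test, a list of 24 genes raised 4-fold at the dispersion of 0.04 ranked 1 of 38, and 0 other lists were called. Its genes were drawn independently and it was not run at the dispersion of these libraries. It therefore cannot tell how often camera calls lists whose genes vary together, as here. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for summaries and plots.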

Results

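Gene expression was counted in 5 libraries labelled as visceral adipose tissue, 1 of a control, 2 of untreated diabetes and 2 of diabetes treated with curcumin, to describe what the diabetes model and the treatment change. Total counts were 27026597 in control 1, 25451001 in diabetes 1, 25378046 in diabetes 2, 27814957 in curcumin-treated 1 and 42422890 in curcumin-treated 2. The control has no replicate, so values given for it have no spread.

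The libraries differed in tissue markers within each group. Adipocyte genes (23 genes, among them the hormones Adipoq and Lep) took 4.72% of the counts of diabetes 2 (95% Wilson interval 4.71% to 4.73%) and 0.526% of curcumin-treated 1 (0.524% to 0.529%). They took 0.0944% of control 1 (0.0932% to 0.0956%), 0.0579% of diabetes 1 (0.0569% to 0.0588%) and 0.0456% of curcumin-treated 2 (0.0450% to 0.0463%). Genes of the epididymal epithelium (18 genes), the duct that lies along the gonadal fat in males, took 4.97% of control 1 (4.97% to 4.98%), 4.42% of diabetes 1 (4.41% to 4.42%) and 5.94% of curcumin-treated 2 (5.93% to 5.95%). Their share was 0.840% in curcumin-treated 1 (0.837% to 0.844%), where a single gene, Crisp1, held 71.0% of it and the median gene of the list was at 1.84 CPM, against 1936 CPM in control 1. Diabetes 2 held 11 such counts in all. Gpx5, a secreted epididymal peroxidase that is not in this list, led control 1 at 29812 CPM, diabetes 1 at 31116 CPM and curcumin-treated 2 at 55412 CPM. It had 2 counts in diabetes 2. Smooth muscle and pericyte genes took 4.24% of curcumin-treated 1 (4.23% to 4.25%) and at most 0.149% of any other library (0.148% to 0.151%). The most abundant transcript of curcumin-treated 1 was Akr1b7, an aldo-keto reductase, at 17874 CPM.

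**Figure D1:**
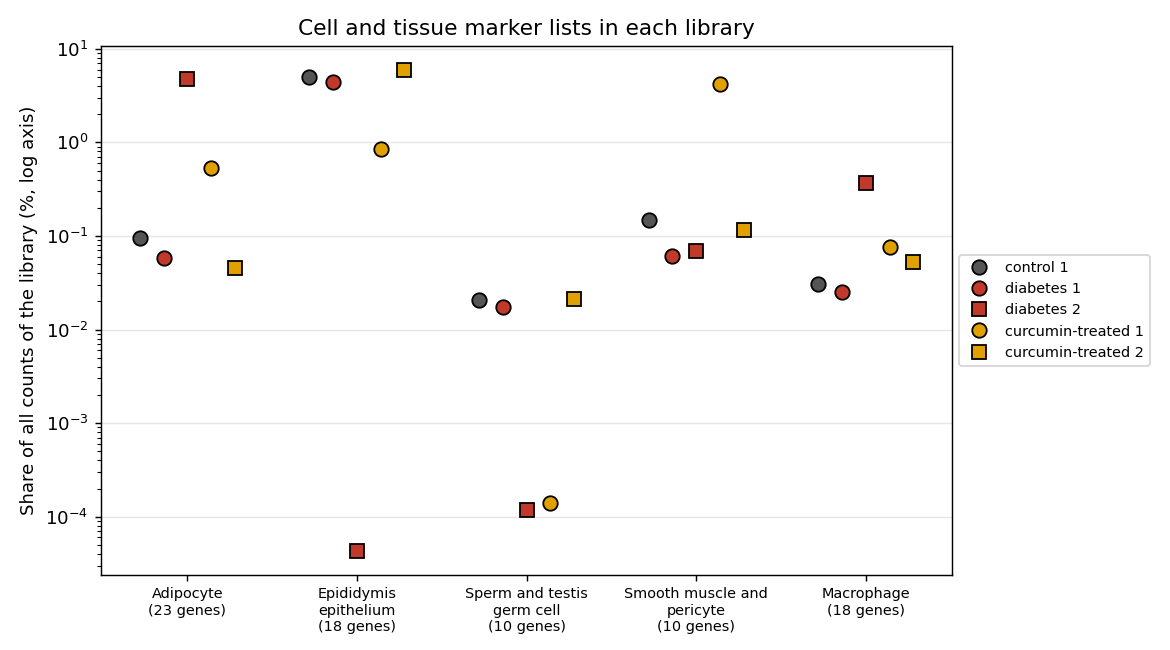
Share of all counts (percent, log axis) taken by 5 marker lists in each of the 5 libraries; each point is 1 library, circles are replicate 1 and squares replicate 2. The adipocyte list takes 4.72% of diabetes 2 and 0.0579% of diabetes 1, while the epididymis list takes 4.42% of diabetes 1.

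Libraries of the same group were not closer as a rule than libraries of different groups. The correlation of log2 CPM across 29855 genes, which are not independent replicates, was 0.714 between the diabetic libraries and 0.824 between the curcumin-treated ones. The diabetic pair lay below all 8 pairs of libraries from different groups, which ran from 0.756 to 0.908, and the curcumin-treated pair lay above 3 and below 5 of them. The highest were control 1 with curcumin-treated 2 (0.908) and control 1 with diabetes 1 (0.889). Diabetes 1 also held few genes with low counts, 1292 genes with 1 to 5 counts. Control 1 held 4216 such genes, diabetes 2 held 10411, curcumin-treated 1 held 19751 and curcumin-treated 2 held 8960.

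**Figure D2:**
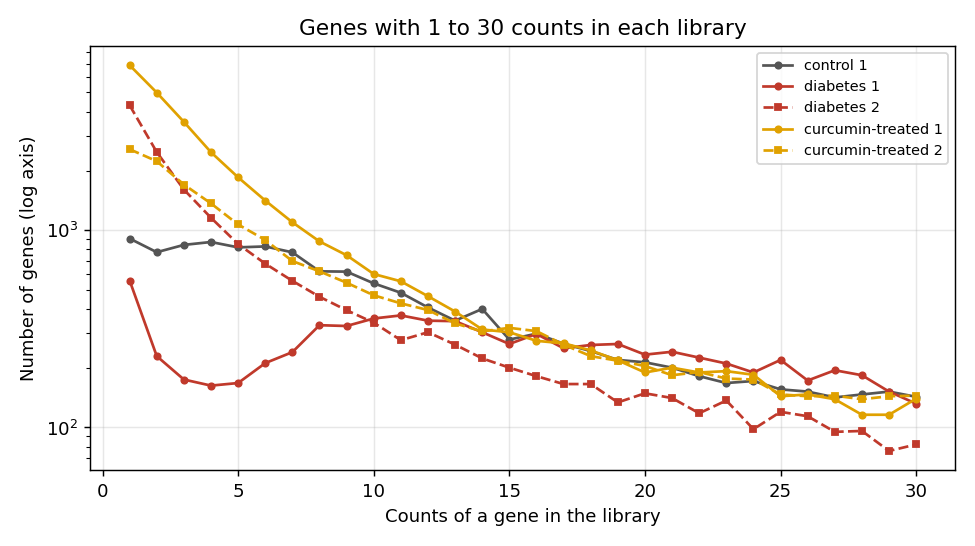
Number of genes (log axis) with each count from 1 to 30 in the 5 libraries; each line is 1 library. Diabetes 1 has 163 genes with 4 counts and 370 with 11, while diabetes 2 has 1157 with 4 and 277 with 11.

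The first comparison asked what curcumin changes in diabetes. Agt (ENSMUSG00000031980), the precursor of angiotensin, was lower in both curcumin-treated libraries, at 9.36 ± 2.69 CPM against 83.9 ± 6.95 CPM in diabetes (SD, n = 2 each; log2 fold change −3.16, SE 0.50). Piezo1 (ENSMUSG00000014444), a mechanically gated ion channel, stood at 13.4 ± 4.77 CPM against 113 ± 55.8 CPM (SD, n = 2 each; log2 fold change −3.09, SE 0.62). Phf1 (ENSMUSG00000024193), a Polycomb-associated protein, was higher with curcumin, at 76.7 ± 16.7 CPM against 16.1 ± 0.795 CPM (SD, n = 2 each; log2 fold change 2.26, SE 0.46). Control 1 held 47.1 CPM of Agt, 63.8 CPM of Piezo1 and 66.9 CPM of Phf1. None of these genes passed the threshold, with an adjusted p of 0.852 for each in edgeR's quasi-likelihood test. Without diabetes 2 the log2 fold change of Piezo1 was −2.47.

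The other genes with the smallest p were Acss3 (ENSMUSG00000035948) at a log2 fold change of −3.20 (SE 0.73), Golm1 (ENSMUSG00000021556) at −2.59 (SE 0.66) and Cmip (ENSMUSG00000034390) at −2.10 (SE 0.54). On the higher side were Ier5l (ENSMUSG00000089762) at 2.29 (SE 0.54), Sv2a (ENSMUSG00000038486), a synaptic vesicle protein, at 4.68 (SE 1.20), Lin7b (ENSMUSG00000003872) at 3.38 (SE 0.86) and Scand1 (ENSMUSG00000046229) at 1.97 (SE 0.50). Each had an adjusted p of 0.852 in edgeR. Sv2a was at 21.2 CPM in curcumin-treated 1 and 3.40 CPM in curcumin-treated 2, and its log2 fold change was 2.83 without the former and 5.45 without the latter. Lin7b was at 2.54 without curcumin-treated 1, and Acss3 at −2.36 without diabetes 2. Across genes, the curcumin difference went with GC content at a rank correlation of 0.328, but the named genes did not all follow it: those on the higher side have a GC content of 54.2% (Sv2a) to 68.4% (Scand1), and on the lower side Piezo1 has 59.0% and Agt 56.3%. With a correction for GC content, chosen after seeing the data, the log2 fold change was 0.51 for Scand1, 1.18 for Ier5l, 1.61 for Phf1, 2.56 for Lin7b, −3.64 for Agt and −3.80 for Piezo1.

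**Figure D3:**
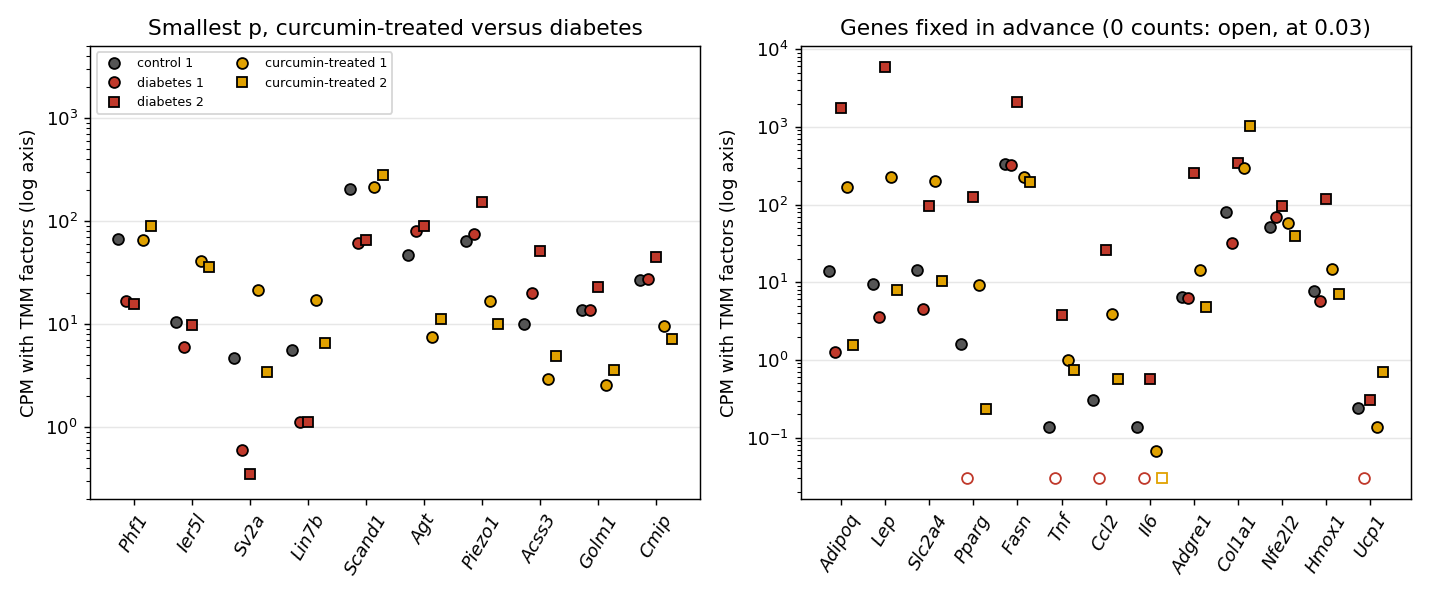
CPM with TMM factors (log axis) of the 10 genes with the smallest p in the curcumin comparison (left) and of the 13 genes reported in any case (right); each point is 1 library, circles are replicate 1 and squares replicate 2, and open points stand for 0 counts. Agt lies at 7.46 and 11.3 CPM in the curcumin-treated libraries and at 79.0 and 88.8 CPM in the diabetic ones.

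Most lipid and macrophage genes had negative fitted fold changes with curcumin, and their lists were highest in diabetes 2. Of 24 lipogenesis genes, 21 had a negative fold change (median −1.38, camera adjusted p = 0.000276 with the preset correlation and adjusted p = 0.924 with an estimated correlation), among them Lpin1 at −3.17 (SE 1.17) and Fasn, the fatty acid synthase, at −2.51 (SE 1.03). Of 17 genes of lipid-associated macrophages, 15 were negative (median −2.40, adjusted p = 0.924 with an estimated correlation), with Spp1, or osteopontin, at −3.48 (SE 1.15) and Gpnmb at −3.13 (SE 1.35). Of 23 adipocyte genes 22 were negative (median −2.89), and of 26 genes of fatty acid oxidation 22 were negative (median −0.90), with Cpt1a at −1.07 (SE 0.46). Both lists had an adjusted p = 0.924 with an estimated correlation. Smooth muscle genes lay on the other side, with 7 of 10 positive (median 4.40, adjusted p = 0.924 with an estimated correlation), and Des at 6.06 (SE 1.60), from 4782 CPM in curcumin-treated 1 and 281 CPM in curcumin-treated 2. In all, 17 of 39 lists passed camera with the preset correlation, 15 down and 2 up, and 0 passed with an estimated correlation (adjusted p = 0.924 or more) or with fry (adjusted p = 0.978 or more). As shares of counts, which abundant genes weigh most, 14 of the 15 lists on the lower side took their highest share of counts in diabetes 2. In 4, both diabetic libraries lay above both curcumin-treated ones: cholesterol synthesis, glucocorticoid targets, complement and liver. The liver list held only 101 to 783 counts per library. Both lists on the higher side took larger shares of both curcumin-treated libraries than of the diabetic ones. Diabetes 1 lay below both curcumin-treated libraries in 4 of the 15. Genes of lipid-associated macrophages took 1.32% of diabetes 2 (95% Wilson interval 1.32% to 1.33%) but 0.137% of diabetes 1 (0.136% to 0.138%), against 0.235% of curcumin-treated 1 (0.233% to 0.237%) and 0.174% of curcumin-treated 2 (0.172% to 0.175%). Macrophage genes took 0.364% of diabetes 2 (0.361% to 0.366%) but 0.0254% of diabetes 1 (0.0247% to 0.0260%), against 0.0759% (0.0749% to 0.0769%) and 0.0528% (0.0521% to 0.0535%) with curcumin. The lipolysis and cell cycle lists were the other 2 of these. Insulin signalling, cell cycle, glucocorticoid targets, lipolysis, complement, macrophage, liver, endoplasmic reticulum stress, antioxidant, cholesterol synthesis and hypoxia genes were the other lists on the lower side, and skeletal muscle genes the other list on the higher side, each with an adjusted p = 0.924 with an estimated correlation.

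Of the 13 metabolic and inflammatory genes chosen in advance, 10 were highest in diabetes 2, Slc2a4 was highest in curcumin-treated 1, and Col1a1 and Ucp1 were highest in curcumin-treated 2. Adipoq was at 1769 CPM in diabetes 2 and 170 CPM in curcumin-treated 1, against 1.27 CPM in diabetes 1 and 1.55 CPM in curcumin-treated 2 (log2 fold change −3.37, SE 2.99). Lep was at 5993 CPM in diabetes 2 and 3.52 CPM in diabetes 1 (−4.67, SE 3.03). The macrophage marker Adgre1 was at 253 CPM in diabetes 2 and 6.22 CPM in diabetes 1 (−3.76, SE 1.67), and the collagen Col1a1 at 32.1 and 342 CPM in diabetes and 294 and 1036 CPM with curcumin (1.83, SE 1.25). The antioxidant regulator Nfe2l2 differed by −0.75 (SE 0.47) and its target Hmox1 by −2.46 (SE 1.35). Slc2a4, the insulin-responsive glucose transporter, differed by 1.09 (SE 1.71), Pparg by −3.73 (SE 3.04), Tnf by −1.13 (SE 2.05), Ccl2 by −2.55 (SE 2.46), Il6 by −2.99 (SE 2.68) and Ucp1 by 1.49 (SE 2.09). Diabetes 1 held 0 counts of Pparg, Tnf, Ccl2, Il6 and Ucp1, so diabetes 2 alone set their diabetic level. The values that follow without diabetes 2 depend on the prior count for Pparg, Tnf, Ccl2 and Ucp1, as does Il6 without curcumin-treated 1. Without diabetes 2 the sign turned for Adipoq (6.06), Lep (5.06), Pparg (10.18), Tnf (7.75), Ccl2 (9.09), Adgre1 (0.61) and Hmox1 (0.96), and without curcumin-treated 1 for Slc2a4 (−2.25). The values without a library ran from −3.30 to −0.60 for Fasn (the latter without diabetes 2), from 0.64 (without curcumin-treated 2) to 4.38 (without diabetes 2) for Col1a1, from −6.05 (without curcumin-treated 1) to −1.96 for Il6 and from 0.47 to 6.72 (without diabetes 2) for Ucp1. Il6 had 13 counts in diabetes 2, 2 in curcumin-treated 1 and 0 in diabetes 1 and curcumin-treated 2, and without diabetes 2 it fell under the low-count filter, as Ucp1 did without curcumin-treated 2, so the sign of neither was tested there.

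Over all 29855 genes, edgeR called 0 genes, with 696 at an unadjusted p under 0.05 against 1493 expected by chance; limma-voom called 0 and DESeq2 called 92, of which 89 were higher. Adjusted over the list alone, 0 genes of any list were called. The libraries of both groups did not overlap for 8391 genes (28.1%), where chance gives 33.3%. Without diabetes 2, 19 lists passed camera, 3 of the 17 lists in the same direction and 4 in the opposite direction, and without curcumin-treated 2, 8 lists passed.

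The second comparison set diabetes against the control. Among the genes that the naming rule admits, those with the smallest p on the higher side were Igha (ENSMUSG00000095079), the constant region of immunoglobulin A, at 5.64 ± 3.47 CPM (SD, n = 2) against 0.205 CPM in control 1 (log2 fold change 4.75, SE 1.16), Ptpn7 (ENSMUSG00000031506) at 11.5 ± 9.52 CPM against 0.240 CPM (5.55, SE 1.56), the immune cell surface molecules Cd83 (5.49, SE 1.94) and Cd86 (3.70, SE 1.35), and Hdac9. Hdac9, a histone deacetylase, had 2 counts in control 1, and its mean in diabetes was 273 times the control level (95% Poisson interval of the control count, 75.6 to 2256). Diabetes 2 held 35.8 CPM of it and diabetes 1 held 1.65 CPM, and its log2 fold change of 8.01 was 4.51 without diabetes 2 and 8.93 without diabetes 1. DESeq2 called it (adjusted p = 0.0402), and the other alternatives gave an adjusted p of 0.498 to 1. On the lower side were Phf1 at 16.1 ± 0.795 CPM against 66.9 CPM (−2.06, SE 0.52), the Hedgehog effector Gli1 (−3.81, SE 0.98), Ssbp4 (−1.81, SE 0.54), AI480526 (−2.49, SE 0.74) and Ankrd9 (−2.53, SE 0.77). None passed the threshold, each with an adjusted p of 1 in edgeR. Without diabetes 2 the log2 fold change was 3.93 for Igha, 4.27 for Ptpn7, 2.98 for Cd83 and 2.92 for Cd86, and without diabetes 1 it was 6.21 for Ptpn7, 6.35 for Cd83 and −3.43 for AI480526. With the GC correction it was −0.86 for Ssbp4 and −1.86 for Ankrd9.

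Most macrophage, adipocyte and lipid genes had positive fitted fold changes with diabetes, but in the macrophage, adipocyte and lipolysis lists the 2 diabetic libraries lay on opposite sides of the control. Of 18 macrophage genes 17 had a positive fold change (median 2.85, camera adjusted p = 0.000325 with the preset correlation and adjusted p = 0.744 with an estimated correlation), among them Ccr2 at 5.01 (SE 2.19). All 23 adipocyte genes (median 4.70) and all 21 lipolysis and lipid droplet genes (median 3.54) were positive, with Mest at 6.69 (SE 3.19) and Plin2 at 6.24 (SE 3.39). Both lists had an adjusted p = 0.744 with an estimated correlation. Macrophage genes took 0.364% of diabetes 2 (95% Wilson interval 0.361% to 0.366%) and 0.0254% of diabetes 1 (0.0247% to 0.0260%), against 0.0307% of control 1 (0.0301% to 0.0314%). Lipolysis genes took 3.85% of diabetes 2 (3.85% to 3.86%) and 0.0403% of diabetes 1 (0.0395% to 0.0411%), against 0.0798% of control 1 (0.0787% to 0.0809%), and the adipocyte share was likewise lower in diabetes 1 (0.0579%) than in control 1 (0.0944%). Inflammation genes were positive for 26 of 29 (median 1.83), T and natural killer cell genes for 15 of 18 (median 2.17) and extracellular matrix genes for 27 of 32 (median 2.93), each list with an adjusted p = 0.744 with an estimated correlation. The share of the T and natural killer cell list went the other way, at 0.0218% of diabetes 1 (0.0212% to 0.0223%) and 0.0123% of diabetes 2 (0.0119% to 0.0127%) against 0.0229% of control 1 (0.0223% to 0.0235%). Klrb1c, a natural killer cell receptor, held 95.0% of that list's counts in control 1 and 93.4% in diabetes 1, so this gene set the direction of the share. Klrb1c led the list only in control 1, diabetes 1 and curcumin-treated 2, which also held the highest epididymis shares. Whether its counts came from natural killer cells was not tested. The list's other genes held 311 counts in control 1 and 363 in diabetes 1, and Il7r alone held 2016 in diabetes 2. All 18 epididymis genes had a negative fold change (median −0.93), as did 8 of 9 sperm and testis germ cell genes (median −1.37), both with an adjusted p = 0.744 with an estimated correlation; diabetes 1 held 4.42% of its counts in epididymis genes. In all, 21 of 39 lists passed camera with the preset correlation, 19 up and 2 down, and 0 passed with an estimated correlation (adjusted p = 0.744 or more) or with fry (adjusted p = 0.935 or more). Of the 19 lists on the higher side, 14 took a smaller share of diabetes 1 than of control 1, and 1 (T and natural killer cells) of diabetes 2. In 5 both diabetic libraries lay above the control: insulin signalling, oxidative phosphorylation, fatty acid oxidation, major histocompatibility complex class II and hypoxia genes. For the class II genes diabetes 1 (0.0379%) and control 1 (0.0369%) had overlapping 95% Wilson intervals.

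Among the genes chosen in advance, Lep had a log2 fold change of 8.30 (SE 4.96), Adipoq of 5.99 (SE 4.65), Pparg of 5.28 (SE 4.49), Ccl2 of 5.37 (SE 3.88), Adgre1 of 4.32 (SE 2.33), Tnf of 3.75 (SE 3.15), Hmox1 of 2.98 (SE 1.84), Fasn of 1.85 (SE 1.31), Slc2a4 of 1.79 (SE 2.26), Col1a1 of 1.21 (SE 1.57), Il6 of 0.99 (SE 2.92), Nfe2l2 of 0.67 (SE 0.59) and Ucp1 of −0.68 (SE 2.53). Without diabetes 2 the value was −1.44 for Lep, −3.45 for Adipoq, −8.65 for Pparg, −6.28 for Ccl2, −0.07 for Adgre1, −5.13 for Tnf, −0.45 for Hmox1, −0.07 for Fasn, −1.68 for Slc2a4, −1.34 for Col1a1 and −5.92 for Ucp1. Without diabetes 1 it was 0.32 for Ucp1 and 2.00 for Il6. Il6 had no value without diabetes 2, where it fell under the low-count filter, and its diabetic counts were all in that library. Diabetes 1 held 0 counts of Pparg, Ccl2, Tnf and Ucp1, so their values without diabetes 2 depend on the prior count.

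EdgeR called 0 of 29855 genes, with 440 at an unadjusted p under 0.05 against 1493 expected by chance; limma-voom called 0 and DESeq2 called 55, of which 48 were higher. Adjusted over the list alone, 0 genes were called. Genes whose diabetic libraries both lay above or both below the control made up 51.1%, where chance gives 66.7%. Without diabetes 2, 3 lists passed camera, 0 of the 21 in the same direction and 1 in the opposite direction; with the replicate block 0 passed.

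The third comparison set curcumin-treated diabetes against the control. By the naming rule, which was fixed for the first 2 comparisons only, the genes with the smallest p on the higher side were Igha at 22.8 ± 6.26 CPM (SD, n = 2) against 0.205 CPM (log2 fold change 6.77, SE 1.28), Angptl6 (ENSMUSG00000038742) at 4.34 (SE 1.39), Ptpn7 at 4.26 (SE 1.46), Tpbg (ENSMUSG00000035274) at 5.93 (SE 2.05) and Sobp (ENSMUSG00000038248) at 3.69 (SE 1.28). On the lower side were Agt at −2.33 (SE 0.54), Cbs (ENSMUSG00000024039), the cystathionine beta-synthase, at −3.09 (SE 0.77), the carbonic anhydrase Car4 (ENSMUSG00000000805) at −4.15 (SE 1.10), Adh6b (ENSMUSG00000074206) at −3.42 (SE 1.04) and Piezo1 at −2.26 (SE 0.67). Each had an adjusted p of 1 in edgeR; DESeq2 called Igha (adjusted p = 0.000775), while the other alternatives gave it an adjusted p of 1 when rounded to 3 digits. Without curcumin-treated 1 the value was 3.59 for Angptl6, 2.72 for Tpbg and −6.10 for Car4, and without curcumin-treated 2 it was 6.83 for Tpbg and −3.36 for Car4.

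In the lists, of 18 T and natural killer cell genes 16 had a positive fold change (median 2.65), as did all 13 tested B cell genes (median 4.55), both lists with an adjusted p = 0.923 with an estimated correlation. B cell genes took 0.0283% of curcumin-treated 1 (95% Wilson interval 0.0277% to 0.0289%) and 0.00336% of curcumin-treated 2 (0.00319% to 0.00354%), against 0.00112% of control 1 (0.000998% to 0.00125%). T and natural killer cell genes took 0.00579% of curcumin-treated 1 (0.00551% to 0.00608%) and 0.0325% of curcumin-treated 2 (0.0320% to 0.0331%), below and above the 0.0229% of control 1. Klrb1c held 91.9% of the list's counts in curcumin-treated 2, where the other genes held 1120 counts, against 311 in control 1. In curcumin-treated 1 Lck led the list, with 298 of 1610 counts. All 35 nuclear genes of oxidative phosphorylation were positive (median 0.60), and 16 of 18 epididymis genes were negative (median −0.53), both with an adjusted p = 0.923 with an estimated correlation. The oxidative phosphorylation list took 0.756% of curcumin-treated 1 (0.753% to 0.759%) but 0.425% of curcumin-treated 2 (0.423% to 0.427%), against 0.426% of control 1 (0.424% to 0.429%). The epididymis share was 0.840% in curcumin-treated 1, mostly from Crisp1, and 5.94% in curcumin-treated 2, below and above the 4.97% of control 1. Of 39 lists 10 passed camera with the preset correlation, 8 up and 2 down, and 0 with an estimated correlation (adjusted p = 0.923 or more) or with fry (adjusted p = 0.990 or more). As shares of counts, 6 of the 8 lists on the higher side lay above the control in both curcumin-treated libraries: inflammation, macrophage, extracellular matrix, major histocompatibility complex class II, B cell and skeletal muscle genes. For inflammation genes curcumin-treated 2 (0.0305%) and control 1 (0.0298%) had overlapping 95% Wilson intervals. Macrophage genes took 0.0759% and 0.0528% of these libraries against 0.0307% of control 1, and matrix genes 1.65% and 0.454% against 0.228%. The 2 lists on the lower side, of the epididymis and of sperm, split.

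Among the genes chosen in advance, the log2 fold change against the control was 3.63 for Lep (SE 3.89), 3.04 for Col1a1 (SE 1.75), 2.88 for Slc2a4 (SE 2.41), 2.82 for Ccl2 (SE 3.40), 2.63 for Tnf (SE 3.01), 2.62 for Adipoq (SE 3.83), 1.55 for Pparg (SE 3.63), 0.80 for Ucp1 (SE 2.49), 0.55 for Adgre1 (SE 1.88), 0.52 for Hmox1 (SE 1.61), −0.08 for Nfe2l2 (SE 0.57), −0.66 for Fasn (SE 1.17) and −2.0 for Il6 (SE 3.15). Adipoq was at 170 and 1.55 CPM in the curcumin-treated libraries against 14.0 CPM in control 1. Without curcumin-treated 1 the value was −3.17 for Adipoq, −0.28 for Lep, −0.46 for Slc2a4, −2.77 for Pparg, −0.45 for Adgre1, −0.12 for Hmox1, 0.87 for Ccl2, −5.06 for Il6, 3.67 for Col1a1 and 1.52 for Ucp1. Without curcumin-treated 2 it was 0.15 for Nfe2l2, 1.84 for Col1a1, −0.98 for Il6, 4.56 for Lep, 3.59 for Adipoq, 3.78 for Slc2a4, 2.49 for Pparg and 3.60 for Ccl2. Il6 without diabetes 2 and Ucp1 without curcumin-treated 2 were again under the low-count filter. The value of Il6 without curcumin-treated 1 depends on the prior count, as curcumin-treated 2 held 0 counts of it.

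EdgeR called 0 genes, with 112 at an unadjusted p under 0.05 against 1493 expected by chance; limma-voom called 0 and DESeq2 called 76, all higher. Libraries did not overlap for 58.7% of genes, where chance gives 66.7%.

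Whether curcumin moved genes opposite to diabetes was read from the correlation, across genes, of the diabetes-minus-control with the curcumin-minus-diabetes difference. It was −0.584, against −0.360 in simulations with no curcumin effect, in which the shared diabetic libraries give a negative value. The simulations drew each gene on its own and redrew the control as well. They leave out the differences in tissue markers between libraries, so they cannot decide whether curcumin reversed the diabetes difference. Without a library the correlation ran from −0.844 to −0.296. The covariance was −1.26 against −1.13 simulated (lowest −1.18). For the 11002 genes of at least 10 CPM the correlation was −0.675 against −0.353 simulated, while the covariance, −0.993, lay within the simulated range (mean −0.985, from −1.08 to −0.903). Of the 500 genes with the smallest p in diabetes against control, 97.8% had the opposite sign with curcumin, against 70.0% simulated. The simulated genes were ranked with the older quasi-likelihood method without robust moderation, so these shares are not strictly alike. With different diabetic libraries on each side, so that none was shared, the correlation was −0.00708 with diabetes 1 against the control and 0.314 with diabetes 2 against the control. Phf1 was among the genes with opposite signs, at −2.06 with diabetes and 2.26 with curcumin. It was named for a small p in both comparisons, which share the diabetic libraries. Its GC content was 58.6%, and across genes the differences went with GC content at rank correlations of −0.216 for diabetes and 0.328 for curcumin.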

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

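The crossed pairing, the adipocyte covariate and the GC correction were chosen after the results were seen; the other alternatives were fixed before the data were examined. The counts of genes past the threshold were 0 under each scaling, filter, threshold, model and left-out library run, with DESeq2 as the exception (92 genes for curcumin-treated against untreated diabetes, 55 for diabetes against control and 76 for curcumin-treated against control). Unadjusted p under 0.05 held for 696, 440 and 112 genes in the main edgeR fit, and limma-voom called 0 in each. In edgeR with the adipocyte covariate it held for 1542, 927 and 472 genes, and with the replicate block for 216, 45 and 75. Chance gives 1493 in each of these fits. The covariate and the block leave fewer residual degrees of freedom than the 2 of the main fit. The lists past the threshold went from 17 and 21 to 0 and 0 with an estimated correlation and with fry. The cause was not tested. Leaving out a replicated library gave 8 to 22 lists for curcumin and 3 to 27 for diabetes.

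With a replicate block, 0 genes were called in each comparison, and the lists numbered 17 for curcumin and 0 for diabetes. The labels do not say that the numbers pair the libraries, and same-numbered libraries deviated in opposite ways (correlation −0.410 across genes, from differences that tissue content may set), so the numbers were not taken as pairs. A shared batch or day is not excluded. With the crossed pairing 0 genes were called in each comparison.

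The correlation of the diabetes and curcumin differences was −0.675 for genes of at least 10 CPM (−0.353 simulated, with a covariance of −0.993 against −0.985 simulated), −0.00708 and 0.314 with separate diabetic libraries, and −0.844 to −0.296 without a library. The separate libraries remove the shared chance values by construction.

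Of 615 recomputed fold changes of named genes, 577 kept their sign and 38 turned, 17 of these without diabetes 2. Without a library, the curcumin values ran from −9.16 to 6.06 for Adipoq, −8.57 to 5.06 for Lep, −2.25 to 4.54 for Slc2a4, −8.05 to 10.18 for Pparg, −2.13 to 7.75 for Tnf, −4.50 to 9.09 for Ccl2, −4.76 to 0.61 for Adgre1 and −3.39 to 0.96 for Hmox1. The diabetes values ran from −3.45 to 6.98 for Adipoq, −1.44 to 9.29 for Lep, −1.68 to 2.71 for Slc2a4, −8.65 to 6.27 for Pparg, −0.070 to 2.63 for Fasn, −5.13 to 4.75 for Tnf, −6.28 to 6.36 for Ccl2, −0.067 to 5.27 for Adgre1, −1.34 to 2.07 for Col1a1, −0.45 to 3.90 for Hmox1 and −5.92 to 0.32 for Ucp1. Against the control, the curcumin-treated values ran from −3.17 to 3.59 for Adipoq, −0.28 to 4.56 for Lep, −0.46 to 3.78 for Slc2a4, −2.77 to 2.49 for Pparg, −0.45 to 1.12 for Adgre1, −0.40 to 0.15 for Nfe2l2 and −0.12 to 0.94 for Hmox1. Il6 without diabetes 2 and Ucp1 without curcumin-treated 2 gave no value, as they fell under the low-count filter. Limma-voom turned the curcumin values of Pparg (0.014), Tnf (1.75) and Ccl2 (1.16) and the diabetes values of Pparg (−0.32) and Il6 (−0.59), and the curcumin-treated against control values of Adipoq (−0.015) and Pparg (−0.31). The replicate block turned Tnf (0.86) and Ccl2 (0.17) for curcumin and Il6 (−0.46) and Col1a1 (−0.88) for diabetes, and Ucp1 (−1.25) for curcumin-treated against control. The cause was not tested beyond the left-out libraries. At the dispersion of these libraries the simulated test recovered 0% of genes changed 64-fold, so the spread between libraries, more than depth, limits the calls.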

Other observations

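The tests of explanations in this part were all chosen after the results they bear on were seen, and the genes named here were picked after their values were seen.

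Sperm transcripts went with the epididymal ones. Prm2, a protamine of sperm chromatin, was at 57.1 CPM in control 1, 56.4 CPM in diabetes 1 and 59.6 CPM in curcumin-treated 2, against 0.315 CPM in diabetes 2 and 0.108 CPM in curcumin-treated 1. Skeletal muscle genes were split between the curcumin-treated libraries. Acta1, the actin of skeletal muscle, was at 1013 CPM in curcumin-treated 1 and 97.0 CPM in curcumin-treated 2, and the creatine kinase Ckm at 279 and 0.155 CPM, but Ttn, or titin, was at 2.22 and 38.8 CPM, and the median of the 12 list genes at 1.92 and 4.85 CPM. Of the 92 genes that DESeq2 called for curcumin, 84 had over 90 percent of the higher group's CPM in a single library and 58 were at 0 in every library of the lower group. Crygc, a lens crystallin, had 221 CPM in curcumin-treated 1 and 0 counts in the other 4 libraries.

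Epididymal and adipocyte transcripts differed within groups. The median epididymis gene differed by 11.68 on the log2(CPM + 0.5) scale between diabetes 1 and diabetes 2, which, with the labels as given, argues against the treatment group as the source. Labels exchanged among the 5 libraries stay open. An exchange with control 1 leaves 1 same-group pair as labelled, so it could not raise both correlations. The other pair stood at 0.760 with diabetes 1 exchanged, 0.889 with diabetes 2, 0.908 with curcumin-treated 1 and 0.845 with curcumin-treated 2. Of the 8 exchanges of 2 labels between groups, 2 leave both same-group correlations (0.861 and 0.864) above both as labelled (0.714 and 0.824). These 2 form the same pairs, diabetes 1 with curcumin-treated 2 and diabetes 2 with curcumin-treated 1, so they are not separate outcomes. Both correlations lie below the highest between groups (0.908), and like tissue content alone would give the same. Epididymis taken with the fat or in its place is a candidate source in control 1, diabetes 1 and curcumin-treated 2. There all 18 list genes reached 1 CPM, against 0 in diabetes 2, and 0 of the 18 genes are in another list. In diabetes 1, Gpx5, which is not in the list, was at 31116 CPM, and Lcn8 and Spag11b were at 4297 and 8276 CPM. In curcumin-treated 1, 13 of the 18 reached 1 CPM, fewer than the 15 set as the bound, so epididymis stays open there. Crisp1 was at 5965 CPM but Gpx5 at 19.6 CPM. The list holds genes of the epididymal epithelium, so it cannot decide on vas deferens, which stays open too. Akr1b7 led that library at 17874 CPM, against at most 8.70 CPM elsewhere (control 1). Smooth muscle and pericyte genes took 4.24% of its counts, against at most 0.149% elsewhere.

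Few genes of diabetes 1 had 1 to 5 counts. Lower depth is argued against, because diabetes 2, of nearly the same total, had 8.06 times as many such genes. Removal of low counts by the authors is argued against by the 556 genes of diabetes 1 with 1 count. Few distinct molecules copied many times stay open as a possible source: genes with 15 to 40 counts (scaled to a total of 25000000) in another library were at 0 in diabetes 1 more often than the other way round for 3 of the 4 libraries, at 29.8% against 21.6% for control 1, 34.3% against 13.2% for curcumin-treated 1 and 27.3% against 13.7% for curcumin-treated 2, but not for diabetes 2, of nearly the same total, at 29.7% against 31.1%. No biological explanation was tested.

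GC-rich genes were lower in both diabetic libraries, with a rank correlation across genes of −0.299 for diabetes 1 and −0.129 for diabetes 2 against the control. The share of epididymal against fat tissue is argued against as the whole source, since the diabetic libraries, far apart in both lists, differed with GC content by −0.01 while curcumin-treated 2 and diabetes 1 differed by 0.268. A GC-dependent yield of the library preparation cannot be told apart from the groups. For the curcumin-treated minus diabetes difference, the rank correlation with GC content within 29 ribosomal protein genes was 0.361 (permutation p = 0.0557, two-sided). The permutation treats these genes as independent. An effect of diabetes and treatment on GC-rich genes stays open, as untested.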
